A study of Homo sapiens with 12 samples.

How the data were processed

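Bulk RNA was sequenced from 10 libraries of A549 and 2 of A375. Per the labels, RNA was extracted with TRIZOL and polyadenylated RNA was made into stranded Illumina libraries. The labels name the A375 control both as cells with a non-targeting guide and as the parental line. They give barasertib by name, beside a code that differs from its usual one, and the group is called barasertib here.

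The authors deposited one table of gene counts per cell line, with raw, unnormalised counts per Ensembl gene and 1 column per library. Whole numbers and column totals that differ between libraries were checked in both tables. The processing notes name TopHat2 2.1, Bowtie 1.1, HTSeq without a version, and the build hg38, and state neither the annotation release nor the strand setting. The A549 table has 32760 genes, 1235 of them at 0 in every library, and the A375 table has 32838, 6794 of them at 0, with 28798 gene identifiers in both. Symbols and coordinates were taken from the tables. Of the 32760 identifiers of the A549 table, 32136 are in GENCODE release 29, and 29646 have the same position there.

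In A549, mitochondrial transcripts took 6.44% to 10.6% of the counts and the 10 most abundant genes 8.41% to 12.7%. Reads carry no molecular identifiers, so every interval and every floor of 3 counts covers counting error alone. Counting intervals are exact (Clopper-Pearson) at the 95% level.

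The A549 libraries were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with its default minimum count of 10, which left 15801, and libraries were scaled by TMM, with factors from 0.896 to 1.08. One quasi-likelihood model (glmQLFit, glmQLFTest) was fitted to the 10 libraries with 1 mean per group, leaving 5 residual degrees of freedom. The 8 comparisons were each treatment against untreated, the 3 pairs of Aurora kinase inhibitors, and the mean of the 3 inhibitors against etoposide. P-values were adjusted by the Benjamini-Hochberg method over all genes of a comparison, and a gene was called at an adjusted p under 0.05. Standard errors are the absolute log2 fold change divided by the square root of the F statistic.

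The 24 gene lists were written from general knowledge before the data were examined, as were the tests, the rule for named genes and most alternatives. They cover senescence markers, DNA replication and G1/S, G2/M and mitosis, p53 targets, SASP factors, genes raised in published senescence profiles, interferon-stimulated genes, NF-kB targets, lysosome, replication-dependent histones, cholesterol biosynthesis and extracellular matrix. They also cover NRF2 targets, the unfolded protein response, antigen presentation, the BCL2 family, MAPK output, SWI/SNF subunits, melanocyte lineage, melanoma dedifferentiation, lung and epithelial, leukocyte and fibroblast markers, and mitochondrially encoded mRNAs. The list of published profiles was written from memory and is not a copy of any one profile. Each list was tested with camera at a preset correlation between genes of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation. With the estimated correlation, the calls against untreated that stayed under 0.05 were p53 targets under all 4 treatments, interferon-stimulated genes under the 3 Aurora inhibitors, G1/S genes under alisertib and barasertib, and histone genes under etoposide. Members were counted over all genes tested and adjusted over the list alone. Where a member had 0 counts in a compared group, list medians were recomputed with that member at its bound, and in every such list they stayed the same to 2 decimals. Of the markers, CDKN2A had no entry in the A549 table, and CDKN2B and AURKC were too low to be tested.

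Named genes followed a rule. AURKA, AURKB, AURKC, TOP2A, TOP2B and the senescence markers are named in every A549 comparison. For each comparison the 5 called genes each way with the largest fitted change were taken among those with an average log2 CPM of at least 3 and, against untreated, with both treated libraries on the same side of both untreated ones. For the genes called under all 4 treatments the 5 each way with the largest smallest change were taken, and for each list up to 4 called members. For A375 SMARCB1 and the 10 genes each way with the most extreme ratio were taken. Locus placeholders and pseudogenes were passed over. Between alisertib and barasertib no gene was called, and OASL, IFIT1 and WISP2 were picked there after their values were seen.

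The A375 libraries have no replicates and were not tested. CPM used TMM-scaled totals, 1 CPM was added to both values before the log2 ratio, and genes with at least 100 counts in 1 library were counted at a 2-fold rule. The median of each list was ranked among 10000 random lists matched on mean expression in 20 bins.

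Alternatives changed 1 choice at a time, except that the lists were also tested without both etoposide libraries and with an estimated correlation together. They were median-ratio (RLE) and library-total scaling, no low-count filter, the replicate number as a block, a test against a fold change of 1.5 (glmTreat), fits of the compared groups alone, DESeq2 1.42.0, and fits without each library in turn. For lists the estimated correlation was an alternative, and for A375 an added 0.25 CPM, a minimum of 20 counts and a 1.5-fold rule. After the 2 etoposide libraries were seen to differ, fits without both of them, limma 3.58.1 voom with 1 weight per group, and GC content and length offsets per library were added. GC content and transcript length were known for 15635 of 15801 genes (98.9%).

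The tests were tested on simulated data. With 200 genes changed and the joint fit's spread in every group, the edgeR test recovered 1.5% of genes changed 1.5-fold, 29.9% of those changed 2-fold and 83.3% of those changed 4-fold, with 6 false calls. With a noisy etoposide pair and the other groups as tight as measured, it recovered 23.9% of 2-fold changes between alisertib and barasertib with 0 false calls, and 80.6% with 1 false call once the etoposide libraries were left out. With that pair noisy but unchanged it made 1430 false calls between etoposide and untreated, voom made 66, and a fit of both groups alone made 0. With changes in that noisy pair, the fit of both groups alone recovered 0% of 4-fold changes, voom 40.9% and the joint fit 80.3%, with 1362 false calls. The camera test called a moved list and 1 of 50 unmoved ones. Co-regulated lists were not simulated, so false calls there are untested. No group has 3 libraries, so no other splits were counted. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.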

Results

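RNA was sequenced from 12 libraries of 2 established human cell lines, 10 from A549, a lung cancer line, and 2 from A375, a melanoma line with a BRAF mutation. The A549 libraries formed 5 groups of 2. The groups were untreated cells, cells given etoposide, a topoisomerase II poison that leaves breaks in DNA, and cells given alisertib, barasertib or tozasertib, inhibitors of the Aurora kinases that carry out mitosis. Alisertib and barasertib were given at 1 µM and tozasertib at 0.2 µM, each for 7 days, and the labels gave no dose or time for etoposide. In A375, 1 library came from control cells and 1 from cells collected 8 days after infection with a virus carrying a guide against SMARCB1, a core subunit of the SWI/SNF chromatin remodelling complex. A549 libraries held 13381820 to 22279482 counts and the A375 libraries 28776512 for the control and 27856002 for the knockout. Group levels are CPM, counts scaled to a common library size (mean ± SD, n = 2), changes are log2 fold changes ± SE, and coordinates are on build hg38. The labels did not say if a group's libraries came from separate cultures, so p-values measured only the spread between these libraries.

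The libraries of each A549 group resembled each other closely except those of etoposide. The log2 ratio between the etoposide libraries had an SD of 0.907 across genes, against 0.256 to 0.304 in the other 4 groups, and 26.7% of genes differed by over 2-fold between them, against 0.835% to 1.80%. The difference followed GC content: the median log2 ratio of etoposide library 2 to library 1 went from 0.984 in the decile of genes with the lowest GC content to -0.723 in the highest. NF-kB target genes had a median log2 change from untreated of 1.06 in etoposide library 1 and -0.85 in library 2. Mitochondrial rRNA took 3.17% and 3.45% of the counts in the etoposide libraries against 1.59% to 2.24% in the other 8, and the 10 most abundant genes 12.7% and 12.6% against 8.41% to 10.1%. For the secretory factors of senescent cells the medians were 1.11 and 0.08, and for extracellular matrix genes 1.36 and 0.14. The medians were 1.21 and 1.34 for p53 target genes, 1.56 and 2.07 for histone genes, 0.81 in both libraries for lysosome genes, and -4.72 and -3.02 for mitosis genes.

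**Figure D1:**
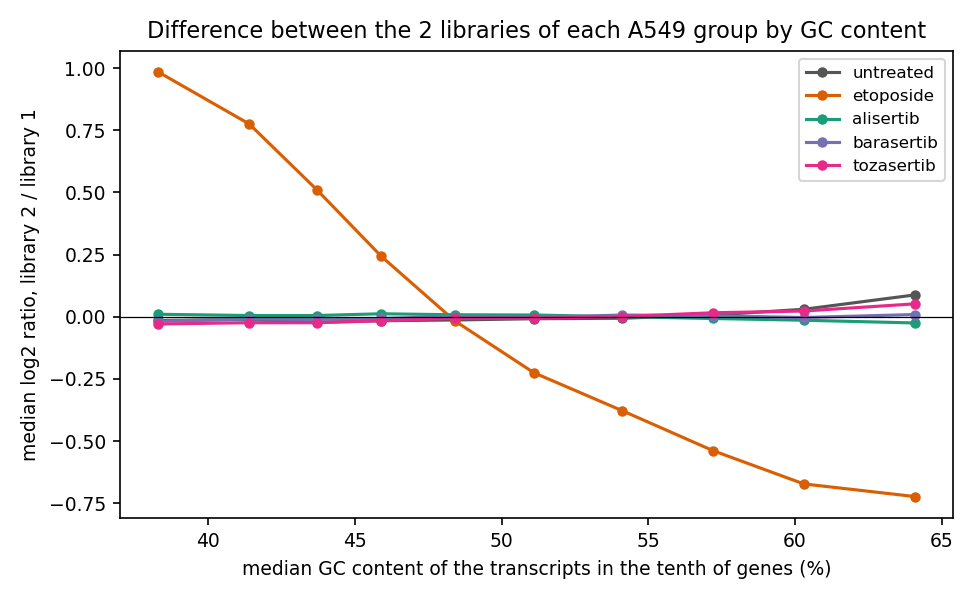
Median log2 ratio of library 2 to library 1 (vertical axis) in 10 deciles of genes by GC content (horizontal axis, low to high), 1 line per A549 group. The etoposide line runs from 0.984 to -0.723.

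The comparison of etoposide with untreated A549 cells asked how the line's expression differed after the DNA-damaging agent, in a series whose stated purpose was to check a gene expression signature of senescence, a lasting arrest of division. With etoposide, genes of cell division fell, while p53 target, histone, lysosome and antigen presentation genes rose. All 35 tested genes of the G2/M and mitosis list fell (35 adjusted over the list alone), with a median of -3.72 (adjusted p = 3.88e-24; adjusted p = 0.179 with an estimated correlation). AURKB, the kinase of chromosome segregation, fell by 4.60 and PLK1, another mitotic kinase, by 4.47. Of 34 DNA replication and G1/S genes, 31 fell and 1 rose (31 and 1 adjusted over the list alone). The list had adjusted p = 1.99e-13, and adjusted p = 0.105 with an estimated correlation. MCM10 stood at -3.51 and the ribonucleotide reductase subunit RRM2 at -2.95. CDKN1A (ENSG00000124762, chromosome 6, 36676460 to 36687339), the inhibitor of cyclin-dependent kinases that p53 induces, rose from 91.2 ± 0.806 to 722 ± 249 CPM, a change of 2.98 ± 0.22 (adjusted p = 6.93e-05). The tetraspanin CD82 (3.47) and SPATA18, which acts in mitochondrial quality control (2.70), were among the 25 of 30 p53 target genes that rose, and 0 fell (28 and 0 adjusted over the list alone; adjusted p = 1.1e-12), or 1 without etoposide library 1. LMNB1 (ENSG00000113368, chromosome 5, 126776623 to 126837020), the nuclear lamina protein lost in senescent cells, fell by 3.99 ± 0.20, from 81.4 ± 1.99 to 5.17 ± 1.3 CPM.

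Of 11 replication-dependent histone genes, 9 rose and 0 fell after etoposide (9 adjusted over the list alone), with HIST1H4H at 3.44, HIST1H2BC at 3.07 and the linker histone HIST1H1C at 3.01 (median 1.68, adjusted p = 6.14e-07). The libraries were made from polyadenylated RNA, whereas most transcripts of these genes carry no poly(A) tail. Of 28 lysosome genes, 18 rose and 0 fell (18 adjusted over the list alone), among them the sterol carrier NPC2 (2.62) and PSAP, the precursor of the saposins (2.03), with adjusted p = 4.76e-08 and adjusted p = 0.105 with an estimated correlation. Without etoposide library 1, 5 of them fell, and 1 without library 2. GLB1, which encodes the lysosomal beta-galactosidase used as a stain for senescence, rose by 1.24 ± 0.14, and FUCA1, a fucosidase, by 1.60. Of 14 antigen presentation genes, 9 rose and 0 fell (10 adjusted over the list alone), among them the class I gene HLA-B (2.97) and its partner B2M (2.48), with adjusted p = 3.06e-06 and adjusted p = 0.176 with an estimated correlation, and 2 and 1 fell without etoposide library 1 and library 2.

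Secretory and inflammatory genes went both ways after etoposide, and their counts hung on single libraries. Of 34 tested factors of the senescence-associated secretory phenotype (SASP), 13 rose and 4 fell (13 and 4 adjusted over the list alone; median 0.81, adjusted p = 0.0471, and adjusted p = 0.717 with an estimated correlation). Without etoposide library 1, 15 rose and 15 fell (adjusted p = 0.476), without etoposide library 2, 24 rose and 5 fell, and without untreated library 1 or 2, 9 or 8 rose. With median-ratio scaling the list gave adjusted p = 0.0526. Among its factors, the chemokine CXCL8 rose by 3.63 ± 0.33 (2.96 without etoposide library 1), the plasminogen activator PLAT by 4.20 (3.47 without library 1) and IGFBP7 by 3.76 (2.45 and 4.41 without library 1 and library 2). IL6 rose by 2.01 ± 0.56 and the protease inhibitor SERPINE1 by 3.89 ± 0.86; these values were 0.55 and 1.5 without etoposide library 1, 2.73 and 4.76 without library 2, and both calls were lost without either untreated library. The growth factor GDF15 rose by 2.42 (1.73 without etoposide library 1). IL1A had 3 counts after etoposide and 1 count in untreated cells, a ratio of 3.77 with a counting interval of 0.303 to 198. Of 20 NF-kB target genes, 3 rose and 2 fell (3 and 2 adjusted over the list alone; adjusted p = 0.606). That was 4 and 12 without etoposide library 1, 15 and 4 without library 2 (adjusted p = 2.19e-09), and 2 and 2 without either untreated library. IRF1, a transcription factor, rose by 1.67, and the chemokine CCL20 fell by 2.56 (-3.53 without etoposide library 1). Of 27 interferon-stimulated genes, 10 rose and 2 fell (11 and 2 adjusted over the list alone; median 0.43, adjusted p = 0.0645, with 0.0382 under library totals and 0.0153 without the low-count filter). The raised genes numbered 3, 5, 14 and 12 and the lowered ones 2, 2, 5 and 4 without untreated library 1, untreated library 2, etoposide library 1 or etoposide library 2. IFI27 rose by 2.62, IFI6 by 2.58 and the ubiquitin-like ISG15 by 2.39. Of 66 tested genes that published profiles report as raised in senescence, 35 rose and 5 fell (37 and 7 adjusted over the list alone; adjusted p = 4.11e-05, and adjusted p = 0.436 with an estimated correlation). The lowered genes numbered 22 without etoposide library 1, 9 without library 2, and 2 without either untreated library.

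The largest rises after etoposide were in CPA4, a carboxypeptidase (ENSG00000128510, chromosome 7, 130293134 to 130324180; 9.64 ± 0.98, and 8.14 without etoposide library 1 or 10.37 without library 2), and in CST4, a salivary cystatin (ENSG00000101441, chromosome 20, 23685640 to 23689040; 7.40 ± 0.32). The cystatin CST2 (7.03), SUGCT, a CoA transferase (6.85), and the secreted protein PIP (6.25) came next. CPA4 had 5 untreated counts, a ratio of 943 with a counting interval of 404 to 2910. SUSD2 fell by 7.77 (-9.17 without etoposide library 1), MKI67, a marker of proliferating cells (ENSG00000148773, chromosome 10, 128096659 to 128126385), by 5.78 ± 0.35 (-6.46 without library 2), and TROAP by 5.25 ± 0.56 (-4.30 without library 1 and -7.14 without library 2). ST6GAL2, a sialyltransferase, fell by 5.14 and MDGA2 by 5.04 (-4.34 and -5.88 without library 1 and library 2). MKI67 went from 373 ± 6.53 to 6.9 ± 3.82 CPM. AURKA fell by 2.33, TOP2B, a target of etoposide, by 1.06 and TOP2A, the other, by 3.96 ± 0.67 (-3.17 and -5.70 without etoposide library 1 and library 2). The chromatin protein HMGB2 fell by 3.06 (-2.46 and -3.93 without library 1 and library 2), and HMGB1 by 1.54 (-1.0 and -2.37, with the call lost without untreated library 1). TP53 (0.27), RB1 (-0.34) and DPP4 (0.23) were not called, and TP53 stood at -0.21 without etoposide library 1 and DPP4 at -1.02 without library 2. Of the 15 tested senescence markers, 7 rose and 4 fell (7 and 4 adjusted over the list alone; adjusted p = 0.481, and 0.000726 without etoposide library 2).

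The edgeR quasi-likelihood test on 15801 genes called 3554 raised and 3130 lowered at an adjusted p under 0.05, 1886 and 1944 of them by at least 2-fold. Under library totals, which shifted the median of all genes by -0.236, the split was 2485 raised and 4460 lowered. Without untreated library 1, untreated library 2, etoposide library 1 or etoposide library 2, 2248, 2035, 5569 and 5879 genes rose and 2039, 1847, 5602 and 5898 fell. Because the 5 groups shared 1 estimate of spread, the etoposide count was too liberal: with a simulated etoposide pair as far apart as this one and no true change, the joint fit made 1430 false calls. A fit of etoposide and untreated alone called 799 raised and 631 lowered, and limma voom with 1 weight per group 1563 and 934. Those fits called, in that order, 23 and 34 lowered mitosis genes, 12 and 21 raised p53 target genes, 6 and 6 raised histone genes, 9 and 15 raised lysosome genes, and 8 and 8 raised antigen presentation genes. They called 15 and 21 lowered G1/S genes, 6 and 13 raised SASP factors, 3 and 3 raised interferon-stimulated genes, and 13 and 27 raised genes of the published profiles.

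**Figure D2:**
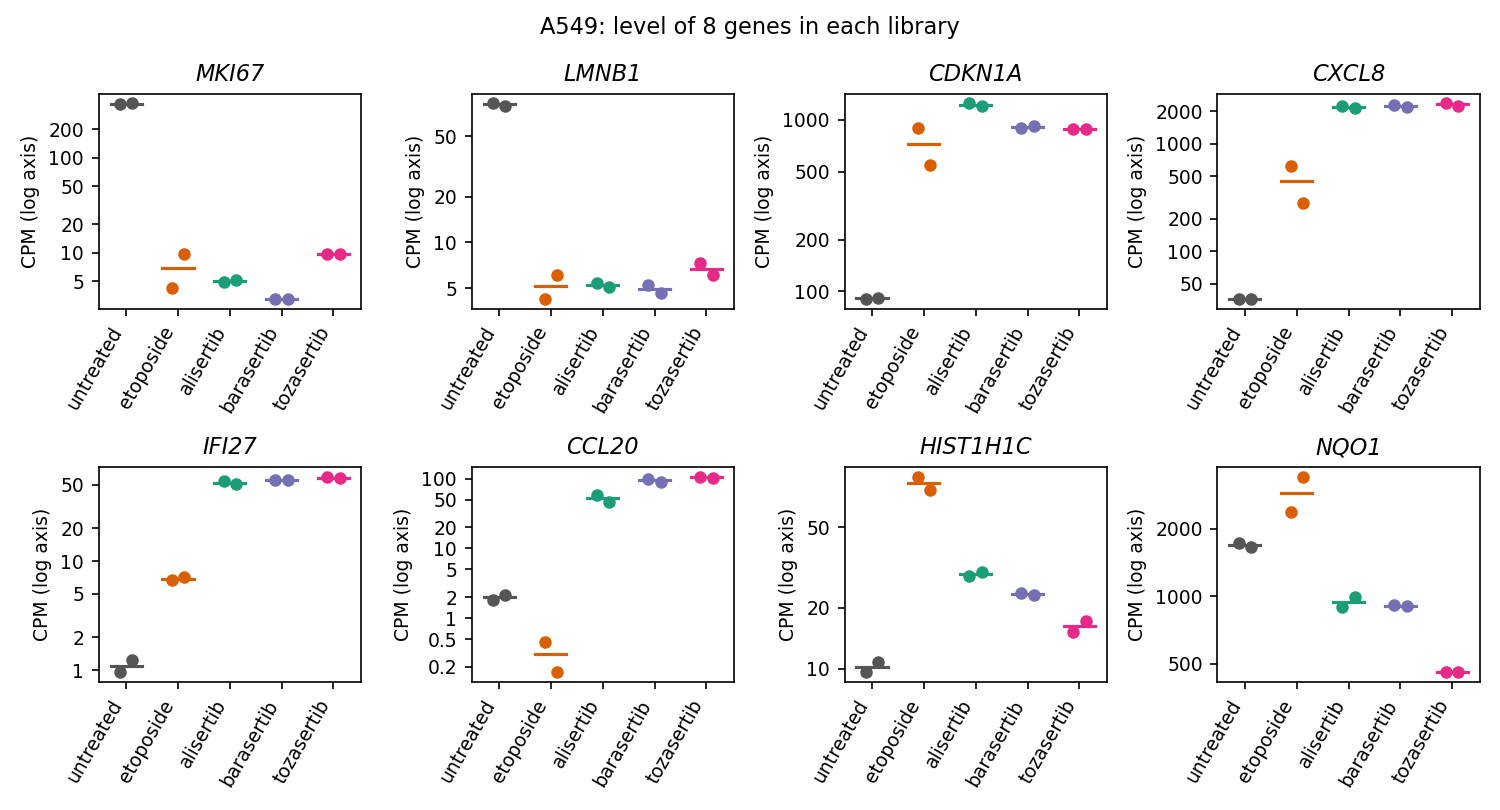
CPM on a log axis of 8 genes in the 5 A549 groups. Points are libraries and the line is the mean of each group. MKI67 and LMNB1 lie below untreated in the 4 treated groups, CDKN1A and CXCL8 above, and CCL20 has a mean of 0.31 CPM after etoposide against 52.1 to 104 CPM with the Aurora inhibitors.

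The comparison of alisertib with untreated cells asked the same question for an inhibitor of Aurora kinases. Alisertib lowered the division genes and raised p53 target, interferon-stimulated, NF-kB and SASP genes. All 35 mitosis genes fell (35 adjusted over the list alone; median -4.59, adjusted p = 2.9e-24, and adjusted p = 0.203 with an estimated correlation), with KIF2C, a kinesin of the centromere, at -5.81 and BIRC5, which encodes survivin, at -5.72. Of 34 G1/S genes, 32 fell and 1 rose (33 and 1 adjusted over the list alone; adjusted p = 1.59e-22), with MCM10 at -6.12 and the replication factor CDC45 at -5.68. Of 27 interferon-stimulated genes, 25 rose and 0 fell (25 adjusted over the list alone; median 2.12, adjusted p = 2e-17), including IFI27 (5.53; 1.1 ± 0.203 to 52.1 ± 2.37 CPM), IFI44 (4.84), IFI6 (4.53) and XAF1 (4.42). Of 30 p53 target genes, 26 rose and 0 fell (27 adjusted over the list alone; adjusted p = 6.82e-15), with CD82 at 4.02 and CDKN1A at 3.75 ± 0.22, from 91.2 ± 0.806 to 1220 ± 36.3 CPM.

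Of 34 SASP factors, 27 rose and 2 fell with alisertib (27 and 3 adjusted over the list alone; median 2.71, adjusted p = 1.91e-09, and adjusted p = 0.203 with an estimated correlation). CXCL8 (ENSG00000169429, chromosome 4, 73740506 to 73743716) went from 36.4 ± 0.0289 to 2190 ± 50.1 CPM (5.91 ± 0.37), CCL20 rose by 4.70 ± 0.22, and IL6 by 3.93 ± 0.60. The macrophage growth factor CSF2, at 0 counts in untreated cells, was at least 12.5-fold higher, counting 3 counts over the untreated group as its floor. IL1A was 86.8-fold higher over 1 untreated count, with a counting interval of 15.1 to 3470. SERPINE1 rose by 5.30 ± 0.92 and GDF15 by 4.19 ± 0.35. Of 20 NF-kB target genes, 17 rose and 0 fell (18 adjusted over the list alone; adjusted p = 4.48e-08, and adjusted p = 0.288 with an estimated correlation). Of 28 lysosome genes, 17 rose and 3 fell (17 and 3 adjusted over the list alone; adjusted p = 0.00074, and adjusted p = 0.203 with an estimated correlation). Of 66 genes of the published profiles, 35 rose and 8 fell (37 and 8 adjusted over the list alone; adjusted p = 1.45e-05, and adjusted p = 0.288 with an estimated correlation). Without any 1 of the 4 compared libraries, the raised counts were 17 to 21 for SASP factors, 9 to 12 for NF-kB targets, 9 to 12 for lysosome genes and 18 to 23 for the published profiles. The lowered ones then numbered 1 for SASP factors, 1 to 2 for lysosome genes and 3 to 4 for the published profiles. Of 14 antigen presentation genes, 12 rose and 0 fell (12 adjusted over the list alone; adjusted p = 1.67e-08, and adjusted p = 0.0999 with an estimated correlation). Of 11 histone genes, 5 rose and 1 fell (5 and 3 adjusted over the list alone; adjusted p = 0.121), with HIST1H1C at 1.52. The lowered one was HIST2H2BE (-1.01), and its call was lost without any 1 of the 4 libraries.

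The largest rises with alisertib were in SBSN, a protein of cornified epithelium (7.55 ± 0.65), CPA4 (7.23), the platelet chemokine PPBP (7.14) and the acute-phase protein SAA1 (6.99). CCL5, an interferon-responsive chemokine, was 207-fold higher over 2 untreated counts, with a counting interval of 57 to 1720. MYBL2 (-7.58 ± 0.34), TROAP (-7.12), MKI67 (-6.21), CCNB2 (-6.19) and ASPM (-6.19) fell most, all genes of dividing cells. AURKA fell by 1.49 and AURKB by 4.59, and TOP2A by 4.69. LMNB1 fell by 3.96, HMGB1 by 2.11 and HMGB2 by 2.67, FUCA1 rose by 1.18, and GLB1 rose by 0.57, a call lost without any 1 of the 4 libraries. TOP2B (-0.36), TP53 (-0.47), RB1 (0.14) and DPP4 (-0.57) were not called. Of the 15 senescence markers, 8 rose and 4 fell (8 and 4 adjusted over the list alone; adjusted p = 0.162, and 1.81e-05 without both etoposide libraries, or 0.101 there with an estimated correlation). The test called 3348 genes raised and 3263 lowered, 2060 and 1805 by at least 2-fold. Leaving out 1 of the 4 libraries gave 1786 to 2065 raised and 1684 to 1968 lowered genes. Library totals, with a median shift of -0.162, gave 2676 raised and 4194 lowered, and a fit without the etoposide libraries, chosen after they were seen to differ, gave 5909 and 5929.

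The comparison of barasertib with untreated cells asked the same question for another inhibitor of these kinases. All 35 mitosis genes fell (35 adjusted over the list alone; median -4.83, adjusted p = 3.94e-26, and adjusted p = 0.172 with an estimated correlation), as did 33 of 34 G1/S genes, with 1 raised (33 and 1 adjusted over the list alone; adjusted p = 1.11e-23). The mitotic kinase NEK2 stood at -6.58 (-7.34 without barasertib library 2) and RRM2 at -5.39. Of 27 interferon-stimulated genes, 26 rose and 0 fell (26 adjusted over the list alone; median 2.91, adjusted p = 3.68e-23), with IFI27 at 5.62, XAF1 at 5.50, IFI44 at 5.44 and OASL, an antiviral protein, at 4.92 (5.54 without untreated library 2). Of 30 p53 target genes, 26 rose and 0 fell (26 adjusted over the list alone; adjusted p = 3.66e-13), with CD82 at 4.06, CDKN1A at 3.32 ± 0.22 and BBC3, which encodes the death protein PUMA, at 2.86. Of 34 SASP factors, 25 rose and 2 fell (26 and 2 adjusted over the list alone; median 2.32, adjusted p = 4.38e-09, and adjusted p = 0.246 with an estimated correlation), with CXCL8 at 5.94, CCL20 at 5.55 and IL6 at 4.44. Of 20 NF-kB target genes, 18 rose and 0 fell (18 adjusted over the list alone; adjusted p = 6.26e-09, and adjusted p = 0.277 with an estimated correlation). ICAM1, an adhesion molecule, rose by 5.25 and the dismutase SOD2 by 3.94. CSF2, at 0 untreated counts, was at least 16.4-fold higher by the same floor, and IL1A 171-fold over 1 untreated count (counting interval 30.2 to 6810).

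Of 28 lysosome genes, 17 rose and 2 fell with barasertib (17 and 3 adjusted over the list alone; adjusted p = 0.000238, and adjusted p = 0.172 with an estimated correlation). Of 14 antigen presentation genes, 13 rose and 0 fell (13 adjusted over the list alone; adjusted p = 1.77e-09, and adjusted p = 0.0852 with an estimated correlation). Of 66 genes of the published profiles, 28 rose and 7 fell (28 and 8 adjusted over the list alone; adjusted p = 0.000238, and adjusted p = 0.355 with an estimated correlation). Of 11 histone genes, 4 rose and 2 fell (4 and 3 adjusted over the list alone; adjusted p = 0.721), with a median of 0.29, a mean of -0.01 and HIST1H1C at 1.20. Without any 1 of the 4 compared libraries, the raised counts were 9 to 12 for lysosome genes, 16 to 18 for the published profiles, 15 to 19 for SASP factors, and 10 to 13 for NF-kB targets. In these fits 1 histone gene was raised and 0 to 1 lowered, and 1 SASP factor, 1 to 2 lysosome genes and 3 to 5 genes of the published profiles were lowered. CCL5 was 319-fold higher over 2 untreated counts (counting interval 87.9 to 2640), and SBSN (6.91), TNFRSF9, a receptor of the TNF family (6.68 ± 1.22), SAA1 (6.58) and IGFN1 (6.43, and 7.02 without untreated library 2) rose most. MYBL2 (-7.66, with -6.85 without barasertib library 1 and -9.23 without library 2), TROAP (-7.14, with -7.79 without library 2), MKI67 (-6.84), KIF2C (-6.58) and the mitotic transcription factor FOXM1 (-6.58 ± 0.21) fell most. AURKA fell by 1.66, AURKB by 4.67, TOP2A by 5.03, LMNB1 by 4.03, HMGB1 by 2.15 and HMGB2 by 2.92. GDF15 rose by 3.61 and FUCA1 by 1.39. GLB1 rose by 0.58, a call lost without any 1 of the 4 libraries, and SERPINE1 by 4.10, a call lost without either untreated library. TOP2B (-0.19), TP53 (-0.48), RB1 (0.49) and DPP4 (-0.15) were not called, and of the 15 senescence markers 8 rose and 4 fell (8 and 4 adjusted over the list alone; adjusted p = 0.122, with 0.0475 without the low-count filter, and 2.93e-06 without both etoposide libraries, or 0.104 there with an estimated correlation). The test called 3179 genes raised and 3034 lowered, 1967 and 1571 by at least 2-fold. The raised genes numbered 1721 to 1966 and the lowered ones 1521 to 1772 without 1 of the 4 libraries. Library totals, with a median shift of -0.106, gave 2790 raised and 3580 lowered, and the fit without the etoposide libraries 5791 and 5827.

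The comparison of tozasertib with untreated cells asked the same question at 0.2 µM. All 35 mitosis genes fell (35 adjusted over the list alone; median -4.02, adjusted p = 1.23e-19, and adjusted p = 0.247 with an estimated correlation), as did 31 of 34 G1/S genes, with 1 raised (32 and 1 adjusted over the list alone; adjusted p = 6.82e-19, and adjusted p = 0.0507 with an estimated correlation). FOXM1 stood at -5.27 and MCM10 at -5.80. Of 27 interferon-stimulated genes, 25 rose and 0 fell (25 adjusted over the list alone; median 2.48, adjusted p = 1.37e-17), with IFI27 at 5.70, IFI44 at 5.15 and XAF1 at 4.98. Of 30 p53 target genes, 25 rose and 1 fell (26 and 1 adjusted over the list alone; adjusted p = 2.7e-10), with CD82 at 4.43 and CDKN1A at 3.28 ± 0.22. Of 34 SASP factors, 26 rose and 3 fell (26 and 4 adjusted over the list alone; median 2.78, adjusted p = 5.37e-08, and adjusted p = 0.287 with an estimated correlation), with CXCL8 at 5.99, CCL20 at 5.70 and IL6 at 4.37. Of 20 NF-kB target genes, 18 rose and 0 fell (18 adjusted over the list alone; adjusted p = 5.37e-08, and adjusted p = 0.337 with an estimated correlation), with ICAM1 at 5.56. CSF2, at 0 untreated counts, was at least 27.4-fold higher by the same floor, and IL1A 137-fold over 1 untreated count (counting interval 24.3 to 5460).

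Of 28 lysosome genes, 15 rose and 2 fell with tozasertib (15 and 2 adjusted over the list alone; adjusted p = 0.00649, and adjusted p = 0.287 with an estimated correlation), with the sialidase NEU1 at 2.17 and the cathepsin CTSZ at -1.17. Without any 1 of the 4 compared libraries, 9 to 10 of them rose. Of 14 antigen presentation genes, 12 rose and 0 fell (12 adjusted over the list alone; adjusted p = 1.55e-07, and adjusted p = 0.129 with an estimated correlation). Of 66 genes of the published profiles, 28 rose and 11 fell (29 and 11 adjusted over the list alone; adjusted p = 0.000852, and adjusted p = 0.345 with an estimated correlation), against 18 to 23 raised and 4 to 6 lowered without 1 library. Of 11 histone genes, 2 rose and 4 fell (2 and 4 adjusted over the list alone; adjusted p = 0.239, and 0.0369 without the low-count filter), with HIST2H2BE at -1.53, against 1 to 2 raised and 2 to 4 lowered without 1 library. IGFN1 (8.28 ± 0.33, and 8.88 without untreated library 2), SAA1 (7.71), SBSN (7.67) and RHCG, an ammonium transporter (7.16), rose most, and CCL5 was 344-fold higher over 2 untreated counts (counting interval 95 to 2850). GPRC6A, an amino acid receptor, had 1 count against 215 untreated counts, a ratio of 0.00407 (counting interval 0.000103 to 0.0229), and its call was lost without any 1 of the 4 libraries. MYBL2 (-5.96), ZWINT (-5.33), PBK (-5.29) and MKI67 (-5.27) fell most. AURKA fell by 1.31, AURKB by 3.90, TOP2A by 4.12, LMNB1 by 3.60, HMGB1 by 2.18 and HMGB2 by 2.61. SERPINE1 rose by 4.79, GDF15 by 3.78 and FUCA1 by 1.13. TP53 fell by 0.89, a call lost without any 1 of the 4 libraries. GLB1 (0.30), TOP2B (-0.11), RB1 (0.44) and DPP4 (-0.58) were not called, and of the 15 senescence markers 7 rose and 5 fell (7 and 5 adjusted over the list alone; adjusted p = 0.234, and 8.72e-05 without both etoposide libraries, or 0.122 there with an estimated correlation). The test called 3724 genes raised and 3647 lowered, 2383 and 1942 by at least 2-fold. With 1 of the 4 libraries left out, 2231 to 2560 genes rose and 2106 to 2357 fell. Library totals, with a median shift of -0.046, gave 3569 raised and 3817 lowered, and the fit without the etoposide libraries 6028 and 6187.

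**Figure D3:**
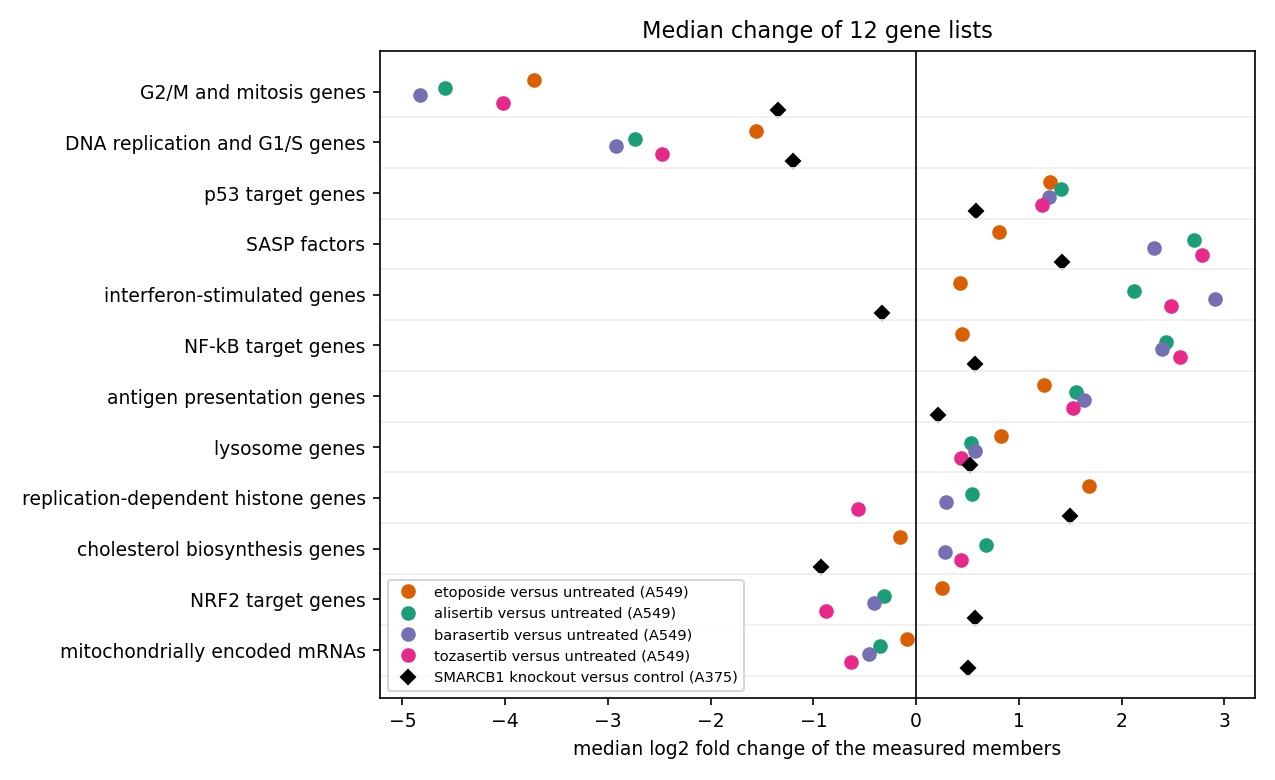
Median log2 fold change against untreated (horizontal axis) of 12 gene lists (vertical axis) for the 4 treatments of A549 (circles), and median log2 ratio of SMARCB1 knockout to control in A375 (black diamonds). For mitosis genes the A549 medians run from -4.83 to -3.72 and the A375 median is -1.34. For interferon-stimulated genes the A375 median is -0.33.

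Taking the 4 treatments together, 1313 genes rose and 1198 fell under every one of them. These counts include the etoposide calls of the joint fit, and voom with 1 weight per group gave 976 and 647, of which 729 and 398 were among them. In the joint fit 966 genes were called in opposite directions in some pair of treatments. The raised genes with the largest smallest change were CPA4, PPBP, TNFRSF9, PIP and DHRS9, a retinol dehydrogenase, whose lowest values among the 4 treatments were 5.93, 5.45, 4.65, 4.58 and 4.50. The lowered ones were MKI67, KIF14, DEPDC1, CENPF and CIT, genes of mitosis and cytokinesis, at -5.27, -4.57, -4.53, -4.50 and -4.48 in the treatment with the smallest fall. Without etoposide library 1, TNFRSF9 stood at 0.85 after etoposide, PPBP at 4.64, KIF14 at -3.99, CENPF at -3.76 and DEPDC1 at -3.67. KIF14, CENPF and DEPDC1 stood at -7.27, -5.85 and -6.53 without library 2, and the TNFRSF9 call was lost without etoposide library 1 or either untreated library. Independent lists of these sizes would share 35.7 raised and 28.6 lowered genes. In 20 simulations of unchanged groups against the same untreated libraries 0 genes were called in all 4. Unchanged groups rarely pass in all 4, so this cannot test the excess. What shared untreated libraries add to it was not separated. Across 15801 genes, which are not independent replicates, the changes of any 2 Aurora inhibitors correlated at 0.932 to 0.959 and those of etoposide with each inhibitor at 0.518 to 0.616. Shared controls alone gave 0.49 to 0.501 and 0.482 to 0.495 in simulation, with a covariance of 0.051 against 1.586 to 1.643 and 0.913 to 1.032 in the data. Without untreated library 1, untreated library 2, etoposide library 1 or etoposide library 2, 698, 622, 2396 and 2829 genes rose under all 4 treatments and 671, 628, 2527 and 2910 fell. Without barasertib library 1 or 2, 785 or 786 fell.

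The direct comparison of the 3 Aurora kinase inhibitors with etoposide, within the fit of all libraries, asked where the kinds of agent differed. Interferon-stimulated and NF-kB genes were higher with the Aurora inhibitors, and histone and NRF2 target genes higher with etoposide. Of 27 interferon-stimulated genes, 26 were higher with the inhibitors and 0 lower (27 and 0 adjusted over the list alone; median 2.14, adjusted p = 3.7e-14, and adjusted p = 0.0669 with an estimated correlation), such as XAF1 (4.65), HERC5 (3.77) and IFI44L (3.74). Of 20 NF-kB targets, 17 were higher and 0 lower (19 adjusted over the list alone; median 1.72, adjusted p = 6.55e-07, and adjusted p = 0.554 with an estimated correlation), with CCL20 at 7.87 ± 0.27 (8.83 without etoposide library 1). Of 34 SASP factors, 18 were higher and 5 lower (18 and 5 adjusted over the list alone; adjusted p = 0.00231, and adjusted p = 0.599 with an estimated correlation), against 7 and 10 lower without etoposide library 1 and library 2. All 11 histone genes were lower (11 adjusted over the list alone; median -1.84, adjusted p = 3.99e-07, and adjusted p = 0.0517 with an estimated correlation), with HIST1H4H at -3.27 and HIST1H2AC at -2.24. Of 19 NRF2 targets, 16 were lower and 1 higher (16 and 1 adjusted over the list alone; median -1.04, adjusted p = 1.49e-05, and adjusted p = 0.488 with an estimated correlation), with the quinone reductase NQO1 at -1.97. Of 23 cholesterol biosynthesis genes, 14 were higher and 1 lower (15 and 1 adjusted over the list alone; adjusted p = 0.00169, and adjusted p = 0.488 with an estimated correlation), with STARD4, a sterol carrier, at 2.64. The lower genes of that list numbered 2 without etoposide library 1 and 7 without library 2. Of 28 lysosome genes, 2 were higher and 15 lower (2 and 16 adjusted over the list alone; adjusted p = 0.00725, and adjusted p = 0.488 with an estimated correlation), with NPC2 at -1.41. Without etoposide library 1 the lysosome list had 6 higher and 17 lower (adjusted p = 0.116), and without library 2, 5 higher and 23 lower. Of 34 G1/S genes, 3 were higher and 22 lower (3 and 23 adjusted over the list alone; adjusted p = 8.4e-06, and adjusted p = 0.453 with an estimated correlation), and 7 higher without etoposide library 2.

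Of 35 mitosis genes, 3 were higher and 8 lower with the inhibitors than with etoposide (3 and 8 adjusted over the list alone; adjusted p = 0.625). There were 5 higher and 26 lower without etoposide library 1 (adjusted p = 0.0452), and 17 higher and 4 lower without library 2. Of 30 p53 targets, 9 were higher and 7 lower (10 and 7 adjusted over the list alone; median -0.01, mean 0.09, adjusted p = 0.934). That was 12 and 14 without etoposide library 1, and 16 and 11 without library 2. GPRC6A (-8.53, with -9.48 and -5.14 without etoposide library 1 and library 2, and -9.22 without tozasertib library 1), the alcohol dehydrogenase ADH1C (-7.36, with -8.25 and -4.85 without etoposide library 1 and library 2), CDH6, a cadherin (-4.82), the bile acid conjugating enzyme BAAT (-4.08, with -4.71 and -2.98 without library 1 and library 2) and SUGCT (-3.74) were lower with the inhibitors. IL23A, a cytokine subunit (5.04), IGFN1 (5.84, and 7.24 without etoposide library 1), CCL5 (5.12, and 6.44 without library 1) and SUSD2 (4.99, and 6.40 without library 1) were higher. AURKA was higher by 0.84, TOP2B by 0.84, IL6 by 2.24 (3.70 and 1.52 without library 1 and library 2), CXCL8 by 2.32 (2.98 without library 1) and GDF15 by 1.44 (2.13 without library 1). IL1A, with 3 counts after etoposide, was 34.8-fold higher with the inhibitors (counting interval 11.8 to 169), and CSF2, at 0 counts after etoposide, at least 15.5-fold. GLB1 was lower by 0.75 (-0.75) and TP53 by 0.89 (-0.89). FUCA1 was lower by 0.37 (-0.37), a call lost under library totals. CDKN1A was higher by 0.46 and RB1 by 0.70, calls lost in 6 and 4 of the 8 fits that left out 1 library. AURKB (0.22), TOP2A (-0.65), LMNB1 (0.12), HMGB1 (-0.60), HMGB2 (0.33), SERPINE1 (0.84), MKI67 (-0.33) and DPP4 (-0.67) were not called. TOP2A stood at -1.44 and 1.09 without etoposide library 1 and library 2, and in that order HMGB1 at -1.14 and 0.23, HMGB2 at -0.26 and 1.21, SERPINE1 at 3.24 and -0.02, MKI67 at -0.84 and 0.35, DPP4 at -1.35 and 0.59, and LMNB1 at -0.14 and 0.38. The test called 4024 genes higher and 4499 lower with the inhibitors, 6072 and 6027 without etoposide library 1, and 6081 without library 2, and voom called 1122 and 1556. Library totals shifted the median of all genes by 0.148 and turned the split to 4805 higher and 3726 lower.

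Alisertib and barasertib shared dose and time, and their comparison asked how responses differed. The edgeR test called 0 genes raised and 0 lowered, with 849 genes at an unadjusted p under 0.05, whereas DESeq2 called 16 and 20 and voom 1466 and 1426. The interval of the difference lay within 2-fold for 11025 of 15801 genes (69.8%), with a median half-width of 0.57. In a fit without the etoposide libraries, chosen after they were seen to differ, 1822 genes were higher with alisertib and 1785 lower, 64 and 88 of them by at least 2-fold, and 83.7% of intervals lay within 2-fold. In that fit 22 of 27 interferon-stimulated genes were lower with alisertib and 0 higher (adjusted p = 3.73e-30), with OASL at -1.45 (interval -1.66 to -1.25) and IFIT1 at -1.06 (interval -1.24 to -0.88). In the fit of all libraries that list had 0 genes called over all genes and 9 lowered adjusted over the list alone, with a median of -0.47 and adjusted p = 2.27e-24. WISP2, a matricellular protein, was higher with alisertib by 1.45 (interval 1.31 to 1.59), at 52.4 against 19.2 CPM, and SERPINE1 by 1.20 (interval 1.13 to 1.27), at 327 against 142 CPM. OASL, IFIT1 and WISP2 were picked after their values were seen. With all libraries no kinase, topoisomerase or senescence marker gene was called. SERPINE1 was at 1.20 ± 0.76, MKI67 at 0.63, GDF15 at 0.59, CDKN1A at 0.42, TOP2A at 0.34, HMGB2 at 0.25, AURKA at 0.17, AURKB at 0.08, LMNB1 at 0.07, HMGB1 at 0.04 and TP53 at 0.01. IL1A was at -0.97 ± 0.26, IL6 at -0.50, DPP4 at -0.42, RB1 at -0.34, FUCA1 at -0.22, TOP2B at -0.17, CXCL8 at -0.03 and GLB1 at 0. In the same fit 19 of 23 cholesterol biosynthesis genes were higher with alisertib and 0 lower, and with all libraries 0 were called either way (2 raised and 0 lowered adjusted over the list alone; adjusted p = 4.5e-09, and adjusted p = 0.101 with an estimated correlation). With all libraries the p53 target (median 0.16), histone (0.33) and unfolded protein response (0.19) lists were higher with alisertib (adjusted p = 0.000734, 1.87e-05 and 0.000209, each 0.0486 with an estimated correlation), with 0, 1 and 2 genes raised adjusted over the list alone. The mitosis (adjusted p = 0.000636), lung (0.0272), mitochondrial mRNA (0.0369) and published profile (0.0438) lists were higher too, but not with an estimated correlation. Without the etoposide libraries the dedifferentiation (adjusted p = 1.67e-20), matrix and MAPK (both 1.45e-06) and SASP lists (0.000327) were also higher with alisertib and the NF-kB list lower (4.33e-08); with an estimated correlation as well, the first 3 had 0.0237 and the others 0.0896 and 0.0845.

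Tozasertib was compared with each of these compounds at a different dose, so dose and compound could not be separated. With alisertib 100 genes were higher and 113 lower than with tozasertib, and with barasertib 20 were higher and 10 lower. ALDH3A1, an aldehyde dehydrogenase (ENSG00000108602, chromosome 17, 19737984 to 19748943), was 3730 ± 19.1 CPM in untreated cells, 5320 ± 594 with alisertib, 4750 ± 52 with barasertib and 920 ± 7.48 with tozasertib. Its differences were 2.53 ± 0.11 for alisertib (adjusted p = 0.000257) and 2.37 ± 0.11 for barasertib (adjusted p = 0.000409) over tozasertib. TXNIP, the thioredoxin-binding protein, was higher by 2.49 and 2.83, and IGFN1 (-2.23 and -1.85) and the stress protein ANKRD1 (-2.07 and -2.63) were lower. SLCO2B1 (2.09), SNAP25-AS1 (1.93) and ASRGL1 (1.61) were higher and SUSD2 (-1.78), EML6 (-1.64) and RECQL4 (-1.49) lower with alisertib than tozasertib. ASRGL1 (1.74), SNAP25-AS1 (1.71) and CLDN2 (1.62) were higher and IL23A (-1.45), CIT (-1.30) and FUS (-0.83) lower with barasertib than tozasertib, and the last 5 of these calls were lost with median-ratio scaling. No kinase, topoisomerase or senescence marker gene was called in either comparison. MKI67, for alisertib and then barasertib over tozasertib, was at -0.94 and -1.57, AURKB at -0.69 and -0.76, AURKA at -0.19 and -0.35, TOP2A at -0.57 and -0.91, TOP2B at -0.25 and -0.08, LMNB1 at -0.36 and -0.43, and HMGB2 at -0.07 and -0.32. CDKN1A was at 0.47 and 0.05, GLB1 at 0.27 and 0.28, TP53 at 0.42 and 0.40, HMGB1 at 0.07 and 0.03, RB1 at -0.30 and 0.05, FUCA1 at 0.05 and 0.27, and DPP4 at 0.01 and 0.43. SERPINE1 was at 0.51 and -0.70, GDF15 at 0.42 and -0.17, CXCL8 at -0.08 and -0.05, IL6 at -0.43 and 0.07, and IL1A at -0.65 and 0.32. Each call of these comparisons except ALDH3A1 was lost when any 1 of the 4 compared libraries was left out, those of list members included. Median-ratio scaling called 10 and 3 genes between barasertib and tozasertib, and library totals, with a median shift of -0.129, called 57 and 168 between alisertib and tozasertib. Histone genes were higher with alisertib than tozasertib (3 raised and 0 lowered of 11, 7 and 0 adjusted over the list alone; median 0.66, adjusted p = 1.27e-09), with HIST1H2AC at 1.28. NRF2 target genes were higher with alisertib (4 and 0 of 19, 6 and 0 adjusted over the list alone; adjusted p = 6e-08, and adjusted p = 0.426 with an estimated correlation), with NQO1 at 1.04. The fit without the etoposide libraries called 3611 and 3257 genes for alisertib against tozasertib and 3044 and 2669 for barasertib, and 0 and 29 of 35 mitosis genes for barasertib against tozasertib (median -0.86). The fit of all libraries called 0 and 0 of them (0 and 4 adjusted over the list alone; adjusted p = 2.34e-11, and adjusted p = 0.477 with an estimated correlation). Against tozasertib the p53 target (adjusted p = 0.000406) and mitochondrial mRNA lists (0.000803) were also higher and the mitosis (0.000406) and interferon-stimulated lists (0.00162) lower with alisertib, and the NRF2 (2.1e-08), interferon-stimulated (4.31e-05), histone (6.96e-05) and mitochondrial mRNA lists (0.0449) higher and the cholesterol (0.000101), G1/S (0.0112) and unfolded protein response lists (0.0246) lower with barasertib, none of them called with an estimated correlation.

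The comparison of SMARCB1 knockout with control A375 cells asked what loss of this chromatin remodelling subunit does to the line's expression, and with 1 library each it had no test. SMARCB1 (ENSG00000099956, chromosome 22, 23786963 to 23834516) itself had 2607 counts in the control and 238 in the knockout, a log2 ratio of -3.18. Division genes were lower in the knockout and secreted factors higher. The median of 35 mitosis genes was -1.34 and that of 34 G1/S genes -1.20, below all of 10000 random lists matched on expression, with 33 and 23 genes at least 2-fold lower and 0 higher. The SASP list had a median of 1.42, with 12 of 23 measured genes at least 2-fold higher and 0 lower, and the median of 28 lysosome genes was 0.52, with 8 higher and 0 lower. The medians were 0.58 for 27 p53 targets and 0.57 for 18 NF-kB targets, with 5 and 4 genes at least 2-fold higher and 0 lower, and each of these 4 medians was above all random lists. The median of 7 histone genes was 1.5 (percentile 99.97) and that of 14 interferon-stimulated genes -0.33 (percentile 4.57). The hormone STC1 (ENSG00000159167, chromosome 8, 23841915 to 23854807) was at 8.80 CPM in the control and 2280 CPM in the knockout, a log2 ratio of 7.86 (7.84 to 8.20). The growth factor AREG (6.17), the growth factor binding protein IGFBP3 (5.76), CLCF1 (4.96), the activin antagonist FST (4.86), NPTX1 (4.71), TCN1 (4.48), CORO2B (4.33) and the receptor kinase MERTK (4.25) followed. PAPPA, a protease of growth factor binding proteins, had 1 count in the control and 1301 in the knockout, with a counting interval of 8.00 to 15.78 for the log2 ratio. ASB2 had 470 counts and 2 counts (interval -10.79 to -5.88), and SERPINF1 (-3.64), GPRIN3 (-3.15), HLX (-2.80), COL4A4 (-2.80), LMO7 (-2.79), FAP (-2.67), PODXL (-2.66) and ACTL8 (-2.64) were lower.

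CDKN1A was at 98.9 CPM in the A375 control and 292 CPM in the knockout, a log2 ratio of 1.55 (1.5 to 1.62), and CXCL8 had a ratio of 2.56. LMNB1 stood at -1.76, HMGB2 at -1.75, MKI67 at -1.49 and HMGB1 at -0.99. SERPINE1 (0.78), GDF15 (0.63), GLB1 (0.05), RB1 (-0.07), TP53 (-0.31) and FUCA1 (-0.38) moved less, and the 12 measured senescence markers had a median of -0.19 (percentile 16.01). The 58 measured genes of the published profiles had a median of 0.13 (percentile 96.96), with 7 at least 2-fold higher and 4 lower. Of 11919 genes with at least 100 counts in 1 library, 746 were at least 2-fold higher and 735 lower, against 653 and 879 under library totals. The genes that rose under all 4 A549 treatments, 888 of them measured, had a median of 0.19 and the 925 that fell one of -0.53, and the middle 95% of random lists of either size ran from -0.08 to -0.01. Ratios had 1 CPM added to both values, while the intervals were computed without it and cover counting error alone, so that an interval can lie outside the printed ratio of a gene with few counts.

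**Figure D4:**
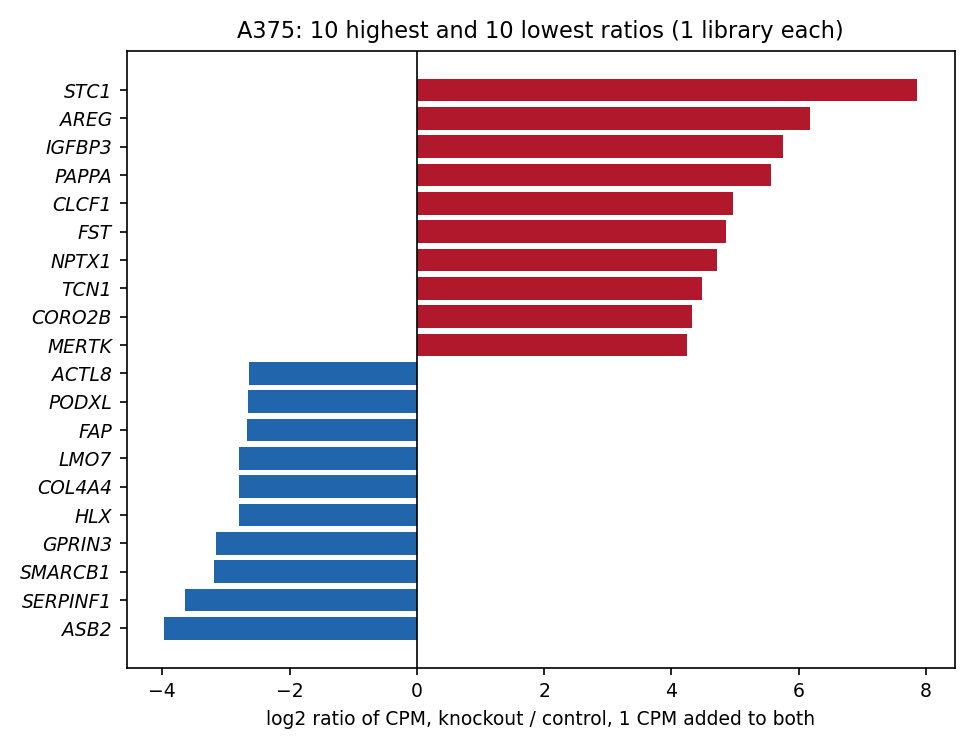
Log2 ratio of SMARCB1 knockout to control in A375 (horizontal axis, 1 CPM added to both values) for the 10 genes with the highest and the 10 with the lowest ratio (vertical axis), from 1 library each. SMARCB1 itself is at -3.18.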

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

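The fits without both etoposide libraries, voom with 1 weight per group, and the GC content and length offsets were chosen after seeing the data. The others were fixed beforehand. A fit without 1 library leaves a lone library, which is assumed to vary like the other groups. Where a count moved, the cause was not tested, except that the test against a fold change asks for a larger change by its construction, and that simulations tried the spread of the etoposide pair. Of simulated 2-fold changes, 29.9% were recovered with the joint fit's spread. With a noisy etoposide pair and tight other groups, 23.9% were recovered between alisertib and barasertib, and 80.6% without the etoposide libraries. Recovery was not simulated at other depths. The 24 list tests kept their call or lack of one in 1892 of 2112 cases, with 162 calls lost, 55 gained and 3 reversed. Of lost calls, 75 fell to the estimated correlation and 57 to it without both etoposide libraries, which changes 2 choices. The named A549 genes kept theirs in 7730 of 8415 cases, with 502 calls lost, 177 gained and 6 reversed. Uncalled sign changes counted as kept. In A375, 201, 86 and 2 of 405 gene ratios moved beyond counting error with library totals, RLE and 0.25 CPM added. All 88 list medians stayed in their spread.

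The reversals with a call follow, with ranges over the fits without 1 library, and the cause was not tested. TP53 ran from -0.206, without etoposide library 1, to 0.643 after etoposide. DPP4 ran from -1.018, without etoposide library 2, to 0.917 after etoposide. Between the Aurora inhibitors and etoposide, TOP2A ran from -1.444 to 1.089, HMGB1 from -1.143 to 0.227, DPP4 from -1.35 to 0.586 and CDK1 from -2.704 to 0.332, each highest without etoposide library 2. The list of MAPK output genes after etoposide turned up without etoposide library 2 (adjusted p = 0.0372, the lowest of a range up to 0.815), and that of extracellular matrix genes between the inhibitors and etoposide turned down in the same setting (adjusted p = 0.047, in a range from 1.22e-05 to 0.189). The list of senescence markers between alisertib and barasertib turned without both etoposide libraries (adjusted p = 0.011, against 0.869 to 0.956 in the fits without 1 library, and 0.0896 with an estimated correlation as well).

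Counts are given as raised and lowered. With median-ratio factors, barasertib against tozasertib gave 10 and 3. With library totals, alisertib against tozasertib gave 57 raised. Without a low-count filter, alisertib against barasertib gave 29 and 39, alisertib against tozasertib 305 and 454, and barasertib against tozasertib 225 and 237. Against a fold change of 1.5, etoposide gave 1780 and 1609, alisertib 1768 and 1496, barasertib 1653 and 1315, tozasertib 2139 and 1775, alisertib against tozasertib 5 and 1, barasertib against tozasertib 3 and 0, the inhibitors against etoposide 2075 and 2339, and the 4 treatments together 567 and 507. In fits of the compared groups alone, etoposide gave 799 and 631, alisertib 5782 and 5766, barasertib 5632 and 5743, tozasertib 6098 and 6121, alisertib against barasertib 1776 and 1726, alisertib against tozasertib 3498 and 3302, and barasertib against tozasertib 3254 and 2923. With DESeq2, alisertib against barasertib gave 16 and 20, alisertib against tozasertib 344 and 306, and barasertib against tozasertib 188 and 91.

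With the replicate block, alisertib against tozasertib gave 23 and 26 and barasertib against tozasertib 3 and 0. The numbers do not pair the libraries, since the deviations of equally numbered libraries correlated at -0.0831 to 0.0391 over 10 pairs of groups. With the replicate block 191 of 192 list tests kept their call, and 27 of 633 named genes lost theirs.

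Without both etoposide libraries, alisertib gave 5909 and 5929, barasertib 5791 and 5827, tozasertib 6028 and 6187, alisertib against barasertib 1822 and 1785, alisertib against tozasertib 3611 and 3257, and barasertib against tozasertib 3044 and 2669. With voom, etoposide gave 1563 and 934, alisertib 5889 and 5899, barasertib 5837 and 5937, tozasertib 6089 and 6258, alisertib against barasertib 1466 and 1426, alisertib against tozasertib 3307 and 3141, barasertib against tozasertib 2907 and 2826, the inhibitors against etoposide 1122 and 1556, and the 4 treatments together 647 lowered. With GC content and length offsets, barasertib gave 4562 lowered, alisertib against tozasertib 888 and 574, barasertib against tozasertib 346 and 127, and the 4 treatments together 1951 lowered.

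Leaving out 1 library at a time, etoposide gave 2035 to 5879 raised and 1847 to 5898 lowered, alisertib 1786 to 2065 and 1684 to 1968, barasertib 1721 to 1966 and 1521 to 1772, and tozasertib 2231 to 2560 and 2106 to 2357. Alisertib against barasertib gave 0 in each of these fits, alisertib against tozasertib 1 raised and 0 lowered, and barasertib against tozasertib 1 raised and 0 lowered. The inhibitors against etoposide gave 3477 to 6081 and 4049 to 6044, and the 4 treatments together 622 to 2829 and 628 to 2910. In A375 a 1.5-fold rule counted 1592 genes higher and 1845 lower, and the other A375 settings gave 653 to 877 higher and 789 to 879 lower.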

Other observations

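Of the tests below, those of a wrong label, of 1 mixing share, of fibroblasts, of leukocytes and of etoposide library 2 in the comparison with the Aurora inhibitors were chosen after the result was seen, and those of GC content and length, of depth and of the mixing range were written before.

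Metabolic and matrix genes moved with the Aurora inhibitors as follows. Of 19 NRF2 target genes, which detoxify and balance redox, 7 fell with alisertib, 10 with barasertib and 14 with tozasertib, and 1 rose with each (the same counts adjusted over the list alone). The list's adjusted p was 0.0211, 0.00752 and 3.57e-05, and with an estimated correlation adjusted p = 0.472, 0.442 and 0.319. Without 1 library 6 or 7 genes fell with barasertib, and 0 to 1, 0 and 0 rose with the inhibitors. After etoposide 9 rose and 2 fell (adjusted p = 0.118, and 2.62e-05 without etoposide library 1), with 5 to 13 raised and 0 to 8 lowered over the fits without 1 library. Of 23 cholesterol biosynthesis genes, 11, 6 and 9 rose with alisertib, barasertib and tozasertib and 2, 5 and 1 fell (the same counts adjusted over the list alone; adjusted p = 0.0151, 0.406 and 0.0277, and adjusted p = 0.363 and 0.359 for the first and last with an estimated correlation). Without 1 library 5 to 7, 3, and 5 to 6 rose and 0 to 1, 1, and 0 fell. After etoposide 2 rose and 6 fell (1 and 5 adjusted over the list alone; adjusted p = 0.107, 0.00157 without etoposide library 1 and 0.0153 without the low-count filter), with 0 to 8 raised and 3 to 14 lowered without 1 library. Of 27 extracellular matrix genes, 14, 12, 12 and 15 rose with etoposide, alisertib, barasertib and tozasertib and 2, 1, 1 and 1 fell (14, 14, 13 and 15 raised adjusted over the list alone). Their adjusted p was 0.0197, 0.000171, 0.000458 and 0.000262, and with an estimated correlation adjusted p = 0.717, 0.42, 0.442 and 0.394. Without 1 library, 6 to 22, 8, 7 to 10, and 9 to 12 rose and 2 to 10, 1, 1 and 1 fell. After etoposide 10 rose and 10 fell without etoposide library 1 (adjusted p = 0.866). Of 13 mitochondrial mRNAs, 7, 8 and 8 fell with the 3 inhibitors and 0 rose (8, 8 and 8 adjusted over the list alone; adjusted p = 0.0601, 0.00759 and 0.00195, and adjusted p = 0.442 and 0.345 for the last 2 with an estimated correlation). For alisertib it was 0.0156 without both etoposide libraries (0.572 with an estimated correlation as well), 0.0313 under library totals, 0.00293 without the low-count filter, and 0.0438 and 0.0178 without untreated library 2 or alisertib library 2. Without 1 library 2 to 4, 3 to 4, and 6 to 7 fell. After etoposide 3 rose and 0 fell (2 and 0 adjusted over the list alone; median -0.09, mean 0.06, adjusted p = 0.726), with 1 to 6 raised and 0 to 5 lowered without 1 library. In A375 the knockout's list medians were 0.57 for 15 NRF2 targets (percentile 99.98), -0.93 for 22 cholesterol genes (percentile 0), 0.52 for 17 matrix genes (percentile 99.94) and 0.51 for 13 mitochondrial mRNAs (percentile 98.72).

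Other lists are given for etoposide, alisertib, barasertib and tozasertib in that order. Of 15 BCL2 family genes 6, 9, 9 and 9 rose and 3, 0, 0 and 0 fell (7, 11, 10 and 10 raised and 4, 0, 0 and 1 lowered adjusted over the list alone; adjusted p = 0.11, 0.000484, 0.000314 and 0.00162, and for the inhibitors adjusted p = 0.203, 0.172 and 0.247 with an estimated correlation). Without 1 library 4 to 9, 6 to 7, 6 to 7, and 8 to 9 rose, 1 to 4 fell after etoposide, and the list had adjusted p = 0.0217 after etoposide without library 2. Of 25 SWI/SNF genes 1, 2, 2 and 1 rose and 13, 10, 11 and 10 fell (15, 12, 13 and 10 lowered adjusted over the list alone; adjusted p = 0.0159, 0.0027, 0.0036 and 0.00829, and adjusted p = 0.128, 0.099, 0.0852 and 0.129 with an estimated correlation). Without 1 library 5 to 18, 7 to 8, 5 to 8, and 9 to 10 of them fell and 1 to 3, 0 to 1, 0 to 1, and 1 to 2 rose, and SMARCB1 fell by 1.31 with alisertib and 1.22 with barasertib. Of 10 melanoma dedifferentiation genes 3, 6, 4 and 7 rose and 1, 0, 0 and 0 fell (4, 7, 6 and 7 raised adjusted over the list alone; adjusted p = 0.419, 0.00119, 0.00459 and 0.00283, and for the inhibitors adjusted p = 0.413, 0.442 and 0.394 with an estimated correlation). Without 1 library 1 to 9, 3 to 5, 3 to 4, and 4 rose and 1 to 4 fell after etoposide (adjusted p = 1.6e-09 without etoposide library 2). Of 16 genes of the unfolded protein response 3, 4, 4 and 5 rose and 4, 7, 7 and 7 fell (3, 5, 4 and 5 and 4, 7, 7 and 7 adjusted over the list alone; adjusted p = 0.633, 0.821, 0.383 and 0.791). Without 1 library 2 to 4, 4, 3 to 4, and 3 to 5 rose and 3 to 9, 7, 6 to 7, and 6 to 7 fell. For alisertib the median (0.12) and mean (0.16) of that list were above 0 and the test pointed down; for tozasertib they were -0.09 and 0.12, and for etoposide -0.14 and 0.03. Of 15 MAPK output genes 2, 6, 4 and 5 rose and 3, 2, 2 and 2 fell (2, 6, 4 and 5 and 3, 2, 3 and 2 adjusted over the list alone; adjusted p = 0.756, 0.25, 0.436 and 0.526). Without both etoposide libraries the MAPK list was called up for the inhibitors (adjusted p = 0.00237, 0.0429 and 0.0271), and not with an estimated correlation as well (adjusted p = 0.0745, 0.131 and 0.122). Without etoposide library 1 the MAPK genes after etoposide numbered 2 raised and 11 lowered, and without library 2, 9 and 3 (adjusted p = 0.0372). With the inhibitors 3 to 4, 3 and 3 rose and 1, 2 and 1 fell without 1 library. Of 4 tested melanocyte genes 1, 0, 1 and 1 rose and 1, 1, 1 and 1 fell (the same counts adjusted over the list alone; adjusted p = 0.756, 0.882, 0.994 and 0.791), the lowered one being the cell cycle kinase CDK2, with 0 to 2, 0, 0 to 1, and 0 to 1 raised and 1 to 2, 1, 1 and 1 lowered without 1 library. Of 11 lung and epithelial genes 4, 5, 3 and 3 rose and 2, 2, 3 and 3 fell (4, 6, 3 and 3 raised and the same lowered adjusted over the list alone; adjusted p = 0.622, 0.389, 0.978 and 0.561), and without 1 library 2 to 5, 1 to 2, 1 to 2, and 2 to 3 rose and 2 to 5, 0 to 1, 1, and 1 to 2 fell. Their medians were -0.11 and -0.02 with etoposide and barasertib, and their means 0.74 and 0.45. In A375 the medians of these lists were 0.12 for 14 BCL2 family genes (percentile 86.91), -0.23 for 24 SWI/SNF genes (5.48), 0.28 for 8 dedifferentiation genes (92.39), 0.14 for 16 unfolded protein response genes (88.96), 0.26 for 15 MAPK genes (96.25), 0.19 for 9 melanocyte genes (83.94) and 0.21 for 13 antigen presentation genes (92.09).

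Of 5 leukocyte markers 2, 2, 1 and 2 rose and 0, 1, 0 and 1 fell with etoposide, alisertib, barasertib and tozasertib (2, 2, 1 and 2 and 1, 1, 0 and 1 adjusted over the list alone; adjusted p = 0.419, 0.25, 0.126 and 0.188, and 0.0491 for tozasertib without the low-count filter). Without 1 library 1 to 2, 2, 1 and 2 rose and 0 to 2, 1, 0 and 1 fell. Of 3 fibroblast markers, of which COL1A1 is also in the matrix list, 2, 2, 1 and 3 rose and 0 fell (2, 3, 3 and 3 raised adjusted over the list alone; adjusted p = 0.2, 0.0482, 0.103 and 0.0358). For alisertib and tozasertib the fibroblast list had adjusted p = 0.203 and 0.247 with an estimated correlation, and 0.403 and 0.249 without both etoposide libraries. Tozasertib's call was also lost without untreated library 1 (0.0523), untreated library 2 (0.0692) or tozasertib library 1 (0.0538), and without 1 library 2 to 3, 1 to 2, 0 to 1, and 1 to 3 of the markers rose and 0 to 1 fell after etoposide. LYZ rose by 5.30, 4.32, 4.52 and 4.49 (6.19, 5.21, 5.41 and 5.38 without untreated library 2), from 0.123 CPM to 5.6, 2.8, 3.21 and 3.14, and LUM by 3.80 and 2.89 with etoposide and tozasertib, from 0.36 CPM to 5.06 and 2.66. The fibroblast list in A375 had a median of -1.43 over 3 genes (percentile 0.36).

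The etoposide libraries differed more than those of any other pair. After a trend on GC content and transcript length was removed, their SD of log2 ratios was still 2.24 times the next largest, and after thinning all 10 libraries to 1 depth 2.73 times, so neither was the whole cause, although the trend took out 44.48% of the variance in that pair and at most 1.85% in the others. Library 2 correlated better with library 1 than with any library of another group, by 0.035, which argues against a wrong label within the series. Untreated cells mixed into library 2 stay open. Of genes over 2-fold apart between library 1 and untreated, 3.2% lay over 2-fold outside that range, under the preset bound of 5. A mixture with 1 share for every gene is argued against by shares 35.2 percentage points apart between lowered and raised genes. Mixing together with GC bias was not tested, and the design gives no biological explanation to test.

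DCN, LUM and LYZ, markers of fibroblasts and leukocytes, were higher in treated A549 libraries. Fibroblasts would bring COL1A2 and COL3A1, but these had 0.0135 of the counts of LUM and DCN over the 8 treated libraries (7 counts against 391 and 128), which argues against fibroblasts as the source. COL1A1, another collagen of fibroblasts, goes the other way for the inhibitors: it had 778 counts in the treated libraries and rose from 1.78 CPM to 4.96, 4.93 and 9.92 with alisertib, barasertib and tozasertib. After etoposide, where LUM and DCN were highest, it was at 0.878 CPM. PTPRC had 0.0285 of the counts of LYZ (14 against 491), above its bound, but its 4 counts at most per library leave leukocytes undecided. No sort or gate is named in the labels, and expression by the treated A549 cells themselves was not tested apart from this.

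Interferon-stimulated and NF-kB genes were higher with the Aurora inhibitors than with etoposide, whose libraries disagree on NF-kB genes. Of the 47 tested members, 46 were higher in all 6 Aurora libraries than in etoposide library 1, the library with the higher NF-kB values, so etoposide library 2 alone does not account for the difference. The doses were not matched and no dose is given for etoposide, so agent and dose stay open as explanations of the difference, and neither was tested.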
